A study of Homo sapiens with 18 samples.

How the data were processed

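RNA was measured in 18 samples of MDA-MB-231 cells, 3 in each of 6 groups formed by 2 hairpin lines and 3 treatments. Per the labels' protocols, 800000 cells per well were plated 24 h before a treatment of 24 h, RNA was purified with QIAzol and miRNeasy kits, ribosomal RNA was removed and libraries were made with an MGIEasy kit. Per the submitters' processing notes, reads were trimmed with cutadapt 4.4, aligned to GRCh38 with STAR 2.7.7a and counted per gene with featureCounts. The deposited values are raw gene counts, per the labels. The annotation release, the strand setting and the featureCounts version are not given in the sources used here, so counts of genes that overlap on opposite strands may hold reads of either.

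The deposited table held 60709 genes with counts. 1 gene had blank counts in every sample and was left out. 2 further lines named no gene, 1 of them with counts, at most 0.01082% of a library. They stayed out of library sizes and tests. Symbols came from a reference gene name table for 60436 genes and from GENCODE release 29 for 257 more, and 16 genes had none. Coordinates were those of GENCODE release 29 on GRCh38 for 58463 genes. Each sample column was mapped to its group by its label, and all were used. Replicate columns were compared in pairs, and none were identical.

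Levels (CPM) are counts scaled by TMM effective library size. Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total 15), which left 15189. Counts were fitted with edgeR 4.0.16 in R 4.3.3 (TMM factors, 1 coefficient per group, all 18 libraries, robust dispersions and quasi-likelihood F tests, 12 residual degrees of freedom). The common dispersion was 0.003951, a biological coefficient of variation of 6.29%. Genes were called at a Benjamini-Hochberg adjusted p below 0.05. The standard error of a log2 fold change was taken from its F statistic, or from the Wald form where F was below 1. The 9 comparisons were erastin or DHA against vehicle within each line, the untreated lines, the difference between lines in each response, and DHA against erastin within each line.

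Lists of genes were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with an inter-gene correlation preset at 0.01, again with the correlation estimated, and with fry. There were 31 lists: the integrated stress response, cytosolic aminoacyl-tRNA synthetases, amino acid transporters, NRF2 targets, glutathione, thioredoxin and peroxide enzymes, ferroptosis drivers and suppressors, iron handling, cholesterol synthesis and uptake, fatty acid synthesis and desaturation, fatty acid oxidation and PPAR targets, lipid droplets, liver X receptor targets, endoplasmic reticulum chaperones and degradation, heat shock, metallothioneins and zinc export, mitosis, DNA replication, p53 targets, immediate early genes, NF-kB targets, interferon response, hypoxia, mesenchymal state and matrix, the insulin-like growth factor system, autophagy and lysosome, cytosolic ribosomal proteins, mitochondrially encoded messenger RNAs, nuclear-retained RNAs, leukocyte markers, luminal epithelial markers, and fibroblast and endothelial markers. The members were written from general knowledge before the data were examined, as were the comparisons, their statistical tests and the alternatives not named below as chosen later. Most tests of explanations were chosen after results were seen, as the closing section says. Lists share members, among them SLC7A11, TFRC, HMOX1, PTGS2, PLIN2, SREBF1, GCLM, GCLC and TXNRD1. Lists with fewer than 5 tested members (nuclear-retained and structural RNAs, and leukocyte markers) were not tested.

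Genes are named by a rule set before the data were examined: 22 key genes, then up to 6 largest rises and 6 largest falls per comparison among called genes with a mean of at least 5 CPM whose libraries did not overlap between the groups, then up to 4 members of each list with the smallest p and members that moved against the rest. For differences between responses the condition on overlap was dropped. Some genes under this rule are not reported here. Folds against a group without counts are given as at least the ratio to 3 counts. With 1 to 3 counts a ratio and its exact binomial 95% interval are given.

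The tests were tested on simulated data drawn from the real means, dispersions and library sizes of 15189 genes. In each comparison 50 genes with at least 10 expected counts were changed at each fold. Called at 1.5-fold and 2-fold were 78% and 88% for erastin in sh-LUC, 70% and 88% for DHA in sh-LUC, 60% and 90% for erastin in sh-IGFBP6, 68% and 88% for DHA in sh-IGFBP6, and 62% and 90% for the untreated lines. For DHA against erastin they were 76% and 92% in sh-LUC and 82% and 84% in sh-IGFBP6. At 3-fold at least 90% were called in each, and 7 to 14 of 14989 unchanged genes were called. In the simulation of DHA in sh-LUC a list of 20 genes changed by 1.5-fold had a camera p of 9.3e-40, 0 of 100 unchanged lists were called, and DESeq2 called 167 changed and 3 unchanged genes. Genes were drawn independently of each other, so the simulated lists do not test the preset correlation where members of a list vary together. Far fewer genes were changed than were called in the real comparisons, so the scaling was not tested under broad changes. Differences between responses were not simulated.

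Alternatives were DESeq2 size factors in edgeR, library size only, no filter, a filter of at least 1 CPM in 3 libraries, the Wald test of DESeq2 1.42.0, only the libraries compared, a replicate block, and each library left out in turn. Leaving out mitochondrial genes, leaving out replicate 3 of sh-IGFBP6 erastin in comparisons without it, and leaving out libraries for the similarity of responses were chosen after the data were seen. Similarity was the Pearson correlation of log2 fold changes. For pairs that share controls, the correlation produced by the controls alone was simulated.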

Results

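The data are RNA-seq gene counts of MDA-MB-231, a triple-negative breast cancer cell line, carrying a short hairpin RNA against IGFBP6 (sh-IGFBP6) or against luciferase (sh-LUC, the control hairpin). IGFBP6 encodes a secreted binding protein of insulin-like growth factor 2. Cells of each line were kept for 24 h with vehicle (0.5% DMSO and 0.5% ethanol), with 200 µM docosahexaenoic acid (DHA, a polyunsaturated fatty acid) or with 2.5 µM erastin, an inhibitor of cystine uptake that induces ferroptosis. Each of the 6 groups held 3 samples, giving 18 libraries. The labels do not state whether the 3 samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

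Gene counts by library were 2708143, 3224979 and 4043424 in sh-LUC control, 5666029, 7937608 and 6859773 in sh-LUC DHA, and 7281095, 7872349 and 7977429 in sh-LUC erastin. They were 2994716, 4660268 and 3678631 in sh-IGFBP6 control, 3174015, 6592609 and 3781915 in sh-IGFBP6 DHA, and 7153762, 4497420 and 609936 in sh-IGFBP6 erastin. Replicate 3 of sh-IGFBP6 erastin stood apart: 54.4% of its counts fell on the mitochondrial ribosomal RNAs MT-RNR1 and MT-RNR2, against 0.035% to 0.504% in the other 17 libraries. It held 278278 counts outside those RNAs. The genes tested numbered 15189. Levels are CPM (counts scaled to 1e6 by TMM effective library size) as mean ± SD with n = 3. Changes are log2 fold changes with their standard error (SE), and genes were called at an adjusted p below 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (edgeR adjusted p).

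**Figure D1:**
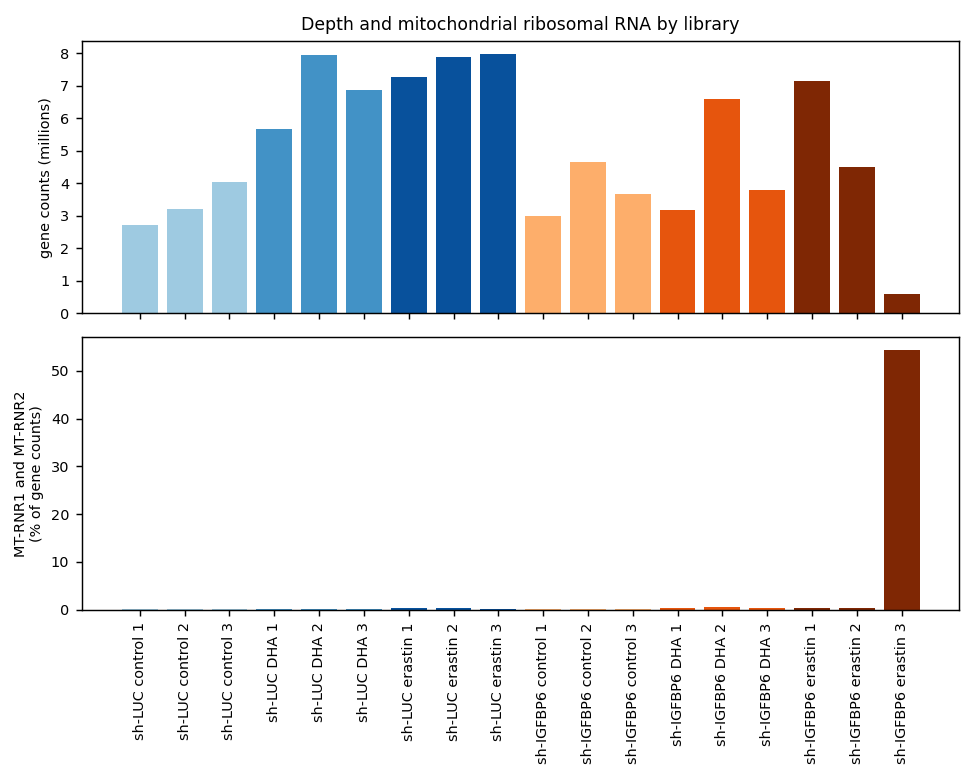
Gene counts per library (upper bars) and the share of MT-RNR1 and MT-RNR2 in percent of gene counts (lower bars) for each of the 18 libraries, coloured by group. Depth ran from 609936 to 7977429 counts, and replicate 3 of sh-IGFBP6 erastin alone had a large mitochondrial ribosomal share (54.4%).

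IGFBP6 itself (ENSG00000167779.9, a protein-coding gene on the plus strand of chromosome 12, positions 53097436 to 53102345 of GRCh38 in GENCODE release 29) was measured in every sample. In CPM it was 20.9, 20.1 and 17.3 in sh-LUC control, 12.3, 14.2 and 15.2 in sh-LUC DHA, and 15.4, 15.5 and 15.3 in sh-LUC erastin. The sh-IGFBP6 libraries gave 0.602, 1.35 and 2.22 in control, 0.901, 1.16 and 0.753 in DHA, and 0.540, 0.420 and 3.81 in erastin, where the last value rests on 1 count. Untreated sh-IGFBP6 cells thus had 1.39 ± 0.807 CPM against 19.4 ± 1.92 in sh-LUC (log2 fold change -3.73, SE 0.27, edgeR adjusted p = 7.3e-26), and all 9 sh-IGFBP6 libraries lay under all 9 sh-LUC libraries. Within sh-LUC cells, IGFBP6 had a log2 fold change of -0.46 after DHA (SE 0.15, edgeR adjusted p = 0.0186) and -0.32 after erastin (SE 0.14, edgeR adjusted p = 0.0606). The DHA call was lost without sh-LUC control replicate 1 (adjusted p = 0.0901), control replicate 2 (0.0947) or DHA replicate 1 (0.0868).

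**Figure D2:**
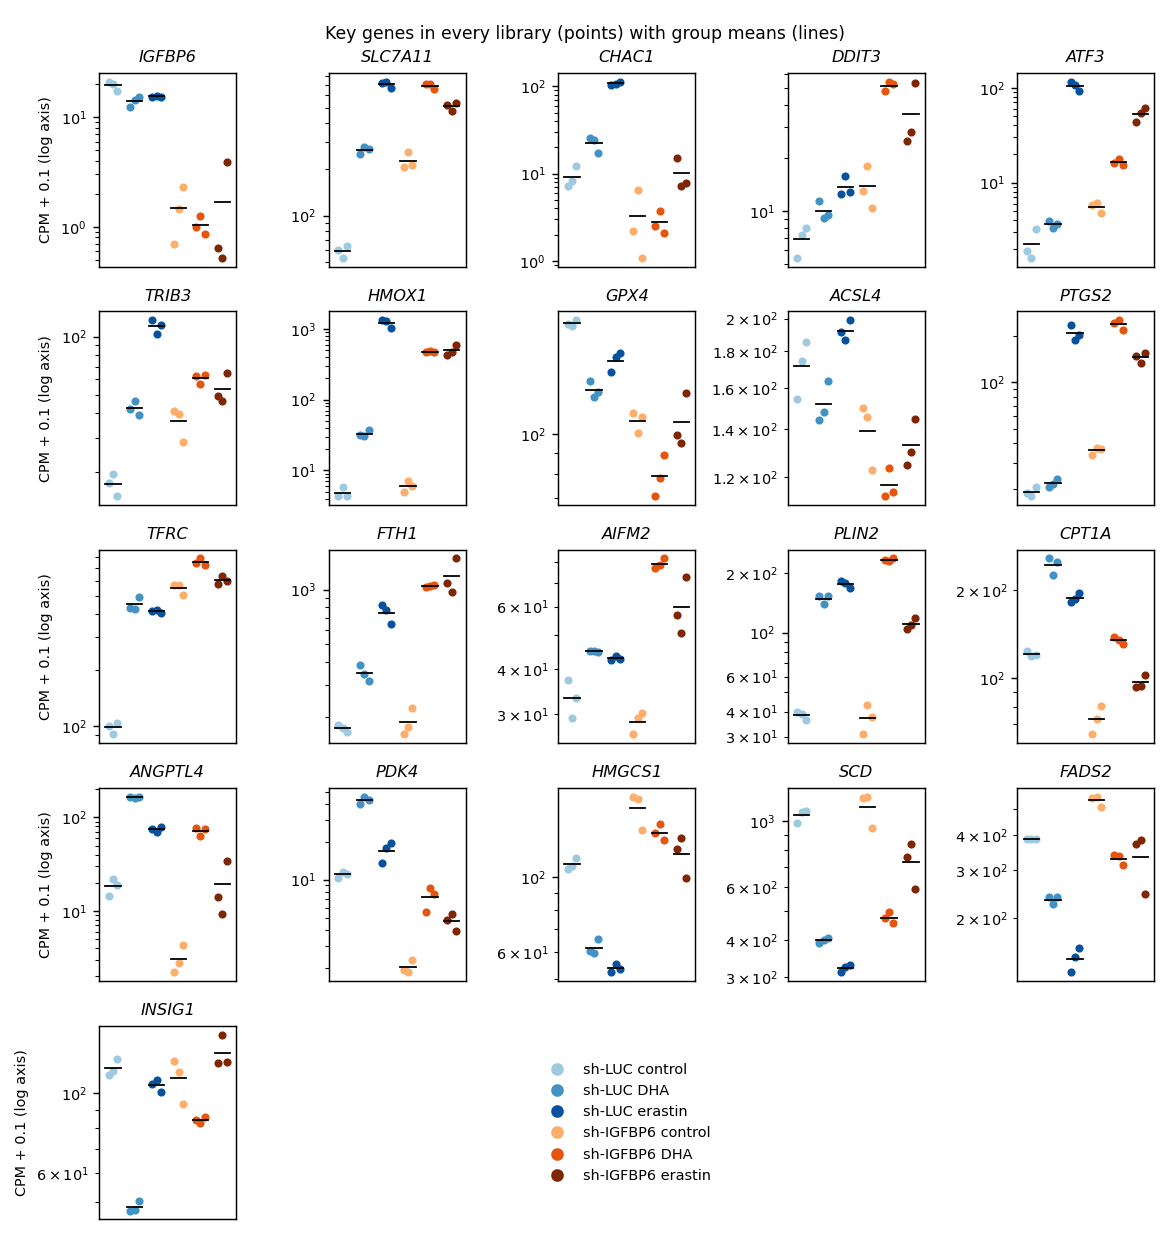
CPM plus 0.1 on a log axis for key genes in each of the 18 libraries (points), coloured by group, with the mean of each group of 3 as a line. SLC7A11 ran from 58.7 CPM in untreated sh-LUC cells to 708 after erastin, and IGFBP6 was lower in every sh-IGFBP6 library than in every sh-LUC library.

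The untreated lines were compared to ask how cells with the IGFBP6 hairpin differ before any compound is added. The difference reached far beyond IGFBP6. NCKAP1L, a subunit of an actin regulatory complex of blood cells, had 239.8 ± 0.905 CPM in sh-IGFBP6 cells and 0 counts in sh-LUC cells, and IL13RA2, which encodes a decoy receptor of interleukin 13, had 46.6 ± 5.21 CPM and 0 counts. INHBB, which encodes an activin subunit, had 195 ± 11.5 CPM in sh-LUC cells and 0 counts in sh-IGFBP6 cells. The transferrin receptor gene and the gene of the cystine transporter that erastin blocks were higher in sh-IGFBP6 cells.

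By edgeR's test 9811 of 15189 genes differed (4936 higher and 4875 lower in sh-IGFBP6), 1855 and 2149 of them by at least 2-fold. The count was 10010 of 15752 tested without replicate 3 of sh-IGFBP6 erastin, a library outside this comparison. Under scaling by library size only the median of all tested genes moved to 0.11. Against a floor of 3 counts in the group at 0, the differences were at least 826-fold for NCKAP1L, 419.7-fold for CCND2, 161-fold for IL13RA2, 118-fold for EPHA3 and 101-fold for SHANK1. In the other direction they were at least 814-fold for INHBB, 499.5-fold for LYPD6B, 389-fold for SLCO2A1, 331-fold for SORCS2 and 278-fold for SHISA2. TIE1, an endothelial receptor gene, had 1 count in sh-LUC and a ratio of 1870 (counting interval 335 to 73910), and COL18A1, a basement membrane collagen gene, had 1 count in sh-IGFBP6 and a ratio of 4523 (811 to 178700). These intervals cover counting error only.

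Among genes tied to ferroptosis, TFRC (log2 fold change 2.47, SE 0.06, edgeR adjusted p = 1.7e-66), SLC7A11 (1.94, SE 0.07, 1.1e-43) and PTGS2 (0.91, SE 0.13, 3.8e-10), a prostaglandin synthase gene induced in ferroptosis, were higher in sh-IGFBP6 cells. GPX4 (log2 fold change -0.79, SE 0.07, edgeR adjusted p = 1.4e-19), the peroxidase that removes lipid hydroperoxides, was lower. Of the ferroptosis drivers and suppressors as a list, 8 were higher, 10 lower and 8 were not called of 26 tested (9 and 10 adjusted over the list alone, camera adjusted p = 0.830, median -0.03, mean 0.14, test direction up). Of iron handling genes, which share TFRC with that list, 7 were higher, 5 lower and 7 were not called of 19 tested (7 and 5 adjusted over the list alone, camera adjusted p = 0.655). The lipid genes ANGPTL4 (log2 fold change -2.61, SE 0.24, edgeR adjusted p = 2.8e-17), PDK4 (-2.50, SE 0.29, 7.7e-14) and CPT1A (-0.73, SE 0.08, 1.0e-15) were lower. Of the same kind, HMGCS1 (log2 fold change 0.55, SE 0.07, edgeR adjusted p = 3.1e-11) and FADS2 (0.47, SE 0.06, 1.0e-10) were higher.

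The matrix genes COL5A1 (log2 fold change -8.68, SE 0.12, edgeR adjusted p = 3.8e-97), THBS1 (-5.17, SE 0.09, 4.8e-88) and FN1 (-2.85, SE 0.07, 2.9e-71) were lower in sh-IGFBP6 cells. TNC (log2 fold change 2.22, SE 0.10, edgeR adjusted p = 1.1e-44) and LOX (1.55, SE 0.08, 1.1e-37) were higher. Of the whole mesenchymal and matrix list, 11 were higher, 16 lower and 4 were not called of 31 tested (11 and 16 adjusted over the list alone, camera adjusted p = 0.449). The lysosomal protease genes CTSD (log2 fold change -4.62, SE 0.07, edgeR adjusted p = 4.0e-91) and CTSB (-1.39, SE 0.07, 2.3e-36) were lower. The inflammatory genes CCL2 (log2 fold change 6.01, SE 0.27, edgeR adjusted p = 2.9e-42), IL1B (5.20, SE 0.19, 8.5e-47) and CXCL8 (2.05, SE 0.16, 2.5e-23) were higher. Of the NF-kB targets, cytokines and chemokines 11 were higher, 7 lower and 3 were not called of 21 tested (11 and 7 adjusted over the list alone, camera adjusted p = 0.271). The interferon genes MX1 (log2 fold change -4.83, SE 0.26, edgeR adjusted p = 4.2e-35) and OAS3 (-2.82, SE 0.12, 6.6e-46) were lower. Of the interferon list 5 were higher, 13 lower and 3 were not called of 21 tested (5 and 13 adjusted over the list alone, camera adjusted p = 0.145).

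Other members of the insulin-like growth factor system were lower along with IGFBP6, among them IGFBP7 (log2 fold change -2.76, SE 0.07, edgeR adjusted p = 1.7e-64), IGFBP4 (-2.95, SE 0.08, 2.4e-52) and the receptor genes INSR (-3.40, SE 0.13, 7.2e-49) and IGF1R (-1.38, SE 0.07, 7.8e-41). Of that list, 1 were higher, 7 lower and 3 were not called of 11 tested (1 and 7 adjusted over the list alone, camera adjusted p = 0.0527). Without 1 of 5 control libraries the list was called (camera adjusted p from 0.0379 to 0.0492), and with an estimated correlation it was not (adjusted p = 0.680). FOXA1, a luminal transcription factor gene, had 1 count in sh-LUC and a ratio of 364 (counting interval 65.0 to 14400). KRT8 (log2 fold change -1.54, SE 0.06, edgeR adjusted p = 3.1e-52) and KRT18 (-0.70, SE 0.06, 9.7e-22) were lower. Of the luminal epithelial list 3 were higher, 7 lower and 1 were not called of 11 tested (4 and 7 adjusted over the list alone, camera adjusted p = 0.447). Of fibroblast and endothelial markers 0 were higher, 4 lower and 2 were not called of 6 tested (0 and 4 adjusted over the list alone, camera adjusted p = 0.270). Among leukocyte markers, 2 were tested and both were lower. Protein synthesis genes were higher as lists. Of cytosolic ribosomal proteins, whose pseudogenes make reads uncertain, 27 were higher, 1 lower and 2 were not called of 30 tested (27 and 1 adjusted over the list alone, camera adjusted p = 5.3e-08, adjusted p = 0.680 with an estimated correlation). Of the aminoacyl-tRNA synthetases 16 were higher, 1 lower and 3 were not called of 20 tested (17 and 1 adjusted over the list alone, camera adjusted p = 5.9e-05, adjusted p = 0.315 with an estimated correlation).

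**Figure D3:**
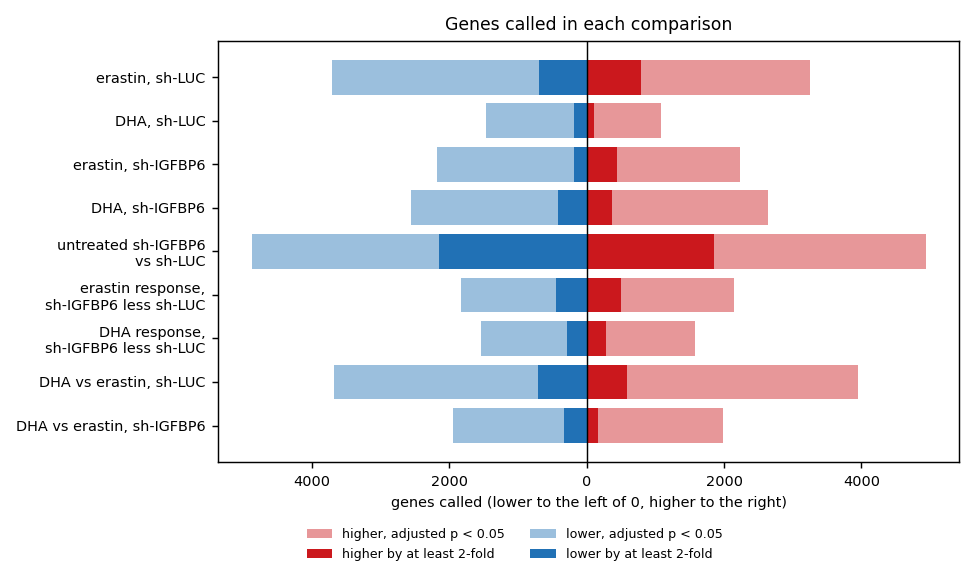
Number of genes called lower (left) and higher (right) by edgeR at an adjusted p below 0.05 in each of the 9 comparisons, with the darker part of each bar for changes of at least 2-fold. The untreated lines differed at 9811 genes, the most of any comparison, and DHA in sh-LUC cells changed 2546, the fewest.

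Erastin in sh-LUC cells was examined to ask what 24 h of blocked cystine uptake does to control cells. The cells raised amino acid stress genes, NRF2 target genes, heat shock genes and immediate early genes. Genes of mitosis and of cholesterol synthesis fell. HMOX1, which encodes heme oxygenase 1, went from 4.76 ± 0.827 to 1209 ± 167 CPM, and the heat shock gene HSPA6 went from 1.05 ± 0.658 to 931 ± 85.1 CPM.

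In all, 3256 genes rose and 3711 fell, 788 and 695 of them by at least 2-fold, and 7055 were called without replicate 3 of sh-IGFBP6 erastin. Of the calls 46.7% were rises, against 31.9% of 4571 calls when scaled by library size only, where the median of all genes moved to -0.12. Without a filter the balance turned, with 3532 rises and 2966 falls. The largest rises by the naming rule were HSPA6 (log2 fold change 9.87, SE 0.31, edgeR adjusted p = 5.8e-12), HMOX1 (7.99, SE 0.17, 5.7e-18), ARC (7.18, SE 0.24, 5.8e-52), ATF3 (5.54, SE 0.17, 6.7e-59) and FOS (5.35, SE 0.17, 1.9e-45). The largest falls were BCL3 (log2 fold change -2.87, SE 0.13, edgeR adjusted p = 1.5e-42), P2RY6 (-2.86, SE 0.20, 5.2e-24), ATOH8 (-2.84, SE 0.18, 1.0e-28), LIPG (-2.42, SE 0.11, 8.1e-41) and the replication-dependent histone gene H3C12 (-2.35, SE 0.14, 1.0e-22).

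The transporter gene itself rose from 58.7 ± 5.18 to 708 ± 36.8 CPM (SLC7A11 (log2 fold change 3.59, SE 0.07, edgeR adjusted p = 9.6e-68)). Targets of ATF4 and CHOP, the factors of the integrated stress response, rose broadly: 21 rose, 0 fell and 3 were not called of 24 tested (23 and 0 adjusted over the list alone, camera adjusted p = 1.3e-21). Among them were PPP1R15A (log2 fold change 3.13, SE 0.07, edgeR adjusted p = 9.6e-68), GDF15 (3.10, SE 0.10, 6.2e-55), PSAT1 (2.58, SE 0.08, 7.8e-52) and TRIB3 (2.73, SE 0.11, 7.9e-46). Of the cytosolic aminoacyl-tRNA synthetases 14 rose, 1 fell and 5 were not called of 20 tested (14 and 1 adjusted over the list alone, camera adjusted p = 3.6e-10). In it YARS1 (log2 fold change 1.63, SE 0.07, edgeR adjusted p = 4.0e-44) and IARS1 (1.21, SE 0.06, 8.7e-41) rose and QARS1 (-0.53, SE 0.06, 3.9e-13) fell. Of the amino acid transporters 10 rose, 0 fell and 4 were not called of 14 tested (11 and 0 adjusted over the list alone, camera adjusted p = 1.5e-11). Among them were SLC3A2 (log2 fold change 2.08, SE 0.06, edgeR adjusted p = 2.7e-61) and SLC7A5 (1.98, SE 0.06, 1.0e-49).

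Targets of the oxidant-sensing factor NRF2 rose too: 17 rose, 1 fell and 3 were not called of 21 tested (18 and 2 adjusted over the list alone, camera adjusted p = 8.1e-13). They included TXNRD1 (log2 fold change 1.79, SE 0.06, edgeR adjusted p = 1.3e-52) and GCLM (1.93, SE 0.07, 5.7e-40), while the reductase gene AKR1C3 (-1.48, SE 0.36, 3.0e-04) fell. In the overlapping list of glutathione, thioredoxin and peroxide enzymes, 9 rose, 9 fell and 6 were not called of 24 tested (10 and 10 adjusted over the list alone, camera adjusted p = 0.210, median -0.01, mean 0.22, test direction up). Ferroptosis genes with rises were PTGS2 (log2 fold change 3.45, SE 0.09, edgeR adjusted p = 3.5e-62), TFRC (2.06, SE 0.06, 1.3e-57) and FTH1 (2.11, SE 0.15, 6.7e-08), a ferritin gene, whereas GPX4 (-0.30, SE 0.06, 4.2e-05) fell. With library size only GPX4 had a log2 fold change of -0.41 with a larger SE (0.20), and its call was lost (adjusted p = 0.110).

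Sterol genes fell together: 0 rose, 23 fell and 2 were not called of 25 tested (0 and 24 adjusted over the list alone, camera adjusted p = 4.2e-15). Examples were LSS (log2 fold change -1.19, SE 0.06, edgeR adjusted p = 1.2e-35) and HMGCS1 (-1.03, SE 0.08, 1.0e-23). Of fatty acid synthesis and desaturation genes 1 rose, 14 fell and 2 were not called of 17 tested (1 and 16 adjusted over the list alone, camera adjusted p = 9.2e-07, adjusted p = 0.0964 with an estimated correlation). They were led by FADS2 (log2 fold change -1.45, SE 0.06, edgeR adjusted p = 5.8e-35) and SCD (-1.70, SE 0.08, 1.8e-17). The lipid droplet coat gene PLIN2 (log2 fold change 2.20, SE 0.08, edgeR adjusted p = 3.6e-50) and the lipase inhibitor gene ANGPTL4 (2.00, SE 0.12, 2.2e-28) rose. Of the lipid droplet list 4 rose, 3 fell and 8 were not called of 15 tested (4 and 3 adjusted over the list alone, camera adjusted p = 0.539). Of fatty acid oxidation and PPAR targets 5 rose, 6 fell and 10 were not called of 21 tested (5 and 6 adjusted over the list alone, camera adjusted p = 0.433).

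Every heat shock gene tested rose: 14 rose, 0 fell and 0 were not called of 14 tested (14 and 0 adjusted over the list alone, camera adjusted p = 6.3e-18). DNAJB1 (log2 fold change 2.40, SE 0.06, edgeR adjusted p = 7.1e-54), HSP90AA1 (1.79, SE 0.07, 4.7e-48) and HSPA1A (5.20, SE 0.11, 1.8e-44) were among them. HSPA1A shares most of its sequence with HSPA1B, so reads of near-identical copies such as these, metallothioneins and histone genes are uncertain between copies. Of metallothioneins and zinc export genes 5 rose, 0 fell and 1 were not called of 6 tested (5 and 0 adjusted over the list alone, camera adjusted p = 5.9e-04). Of immediate early genes 15 rose, 2 fell and 0 were not called of 17 tested (15 and 2 adjusted over the list alone, camera adjusted p = 2.6e-11). Among them were JUN (log2 fold change 2.73, SE 0.06, edgeR adjusted p = 7.2e-68), DUSP1 (3.12, SE 0.09, 1.6e-62) and ZFP36 (3.18, SE 0.10, 1.2e-57). Hypoxia genes such as PFKFB3 (log2 fold change 1.79, SE 0.07, edgeR adjusted p = 3.6e-48) and ADM (2.69, SE 0.09, 3.2e-46) rose. Of that list 16 rose, 2 fell and 3 were not called of 21 tested (17 and 2 adjusted over the list alone, camera adjusted p = 5.6e-09). Every mitosis gene tested fell: 0 rose, 22 fell and 0 were not called of 22 tested (0 and 22 adjusted over the list alone, camera adjusted p = 5.0e-19). KIF20A (log2 fold change -2.05, SE 0.08, edgeR adjusted p = 7.4e-50), TOP2A (-1.28, SE 0.05, 3.3e-44) and PLK1 (-1.86, SE 0.08, 1.9e-42) had the smallest p. Of DNA replication genes 2 rose, 10 fell and 12 were not called of 24 tested (2 and 10 adjusted over the list alone, camera adjusted p = 0.523, median 0.02, mean -0.06, test direction down).

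Of p53 target genes 6 rose, 2 fell and 9 were not called of 17 tested (6 and 2 adjusted over the list alone, camera adjusted p = 0.00923, adjusted p = 0.298 with an estimated correlation). Among them was CDKN1A (log2 fold change 1.45, SE 0.07, edgeR adjusted p = 2.4e-38). The list was lost when its 6 libraries were fitted alone (camera adjusted p = 0.0652). The mitochondrially encoded messenger RNAs made up 8.03 ± 1.67% of counts after erastin against 2.88 ± 0.235% before. Among them 11 rose, 0 fell and 2 were not called of 13 tested (13 and 0 adjusted over the list alone, camera adjusted p = 2.6e-04, adjusted p = 0.393 with an estimated correlation). Among nuclear-retained and structural RNAs 3 of 4 rose.

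DHA in sh-LUC cells was examined to ask what a polyunsaturated fatty acid does to control cells. Its effect was smaller than that of erastin. Genes of fatty acid use rose, genes of sterol and fatty acid synthesis fell, and the amino acid stress and NRF2 genes rose more mildly. ANGPTL4, a target of the fatty acid receptors, went from 18.4 ± 3.73 to 163 ± 3.88 CPM.

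In all, 1084 genes rose and 1462 fell, 101 and 179 of them by at least 2-fold, and 2596 were called without replicate 3 of sh-IGFBP6 erastin. The count was 756 when scaled by library size only. Without a filter the balance turned, with 1257 rises and 853 falls. The largest rises were ANGPTL4 (log2 fold change 3.13, SE 0.10, edgeR adjusted p = 3.8e-44), HMOX1 (2.79, SE 0.25, 1.4e-07), TFRC (2.18, SE 0.06, 1.9e-59), SLC7A11 (2.17, SE 0.07, 5.8e-47), PHGDH (2.13, SE 0.20, 1.0e-16), which opens serine synthesis, and PDK4 (1.97, SE 0.14, 8.9e-25), a brake on glucose oxidation. The largest falls were the BMP-responsive genes ATOH8 (log2 fold change -5.13, SE 0.25, edgeR adjusted p = 3.9e-38) and ID3 (-2.77, SE 0.16, 5.0e-18), then PTPRQ (-2.26, SE 0.24, 5.2e-14), SPTSSB (-2.12, SE 0.19, 3.1e-18), GABBR2 (-1.88, SE 0.23, 3.3e-11) and COL9A2 (-1.78, SE 0.19, 1.7e-14).

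Of fatty acid oxidation and PPAR targets 10 rose, 2 fell and 9 were not called of 21 tested (11 and 5 adjusted over the list alone, camera adjusted p = 3.9e-06). Among them were PLIN2 (log2 fold change 1.96, SE 0.08, edgeR adjusted p = 1.3e-43) and CPT1A (1.01, SE 0.06, 9.3e-28), which carries fatty acids into mitochondria. Of the sterol list 0 rose, 21 fell and 4 were not called of 25 tested (0 and 22 adjusted over the list alone, camera adjusted p = 3.0e-23). In it INSIG1 (log2 fold change -1.29, SE 0.08, edgeR adjusted p = 2.6e-29) and HMGCS1 (-0.83, SE 0.08, 3.3e-17) fell. Of the fatty acid synthesis list 0 rose, 11 fell and 6 were not called of 17 tested (0 and 12 adjusted over the list alone, camera adjusted p = 7.0e-10, adjusted p = 0.0620 with an estimated correlation). In it SREBF1 (log2 fold change -1.25, SE 0.07, edgeR adjusted p = 2.1e-34) and SCD (-1.39, SE 0.08, 1.2e-14) fell. Liver X receptor targets share SREBF1, and of them 0 rose, 3 fell and 6 were not called of 9 tested (0 and 3 adjusted over the list alone, camera adjusted p = 0.0104, adjusted p = 0.0794 with an estimated correlation). Among them were ABCA1 (log2 fold change -1.15, SE 0.11, edgeR adjusted p = 7.2e-14) and MYLIP (-1.02, SE 0.14, 7.4e-10).

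Integrated stress response genes rose: 18 rose, 1 fell and 5 were not called of 24 tested (19 and 1 adjusted over the list alone, camera adjusted p = 4.3e-20). PSAT1 (log2 fold change 1.45, SE 0.08, edgeR adjusted p = 7.3e-29), SHMT2 (0.84, SE 0.06, 1.5e-22), MTHFD2 (1.16, SE 0.11, 3.7e-17) and TRIB3 (1.33, SE 0.12, 9.7e-17) were examples. DDIT3 was not called (log2 fold change 0.49, SE 0.21, edgeR adjusted p = 0.0949). Of the aminoacyl-tRNA synthetases 14 rose, 0 fell and 6 were not called of 20 tested (14 and 0 adjusted over the list alone, camera adjusted p = 3.7e-13). Of the amino acid transporters 8 rose, 2 fell and 4 were not called of 14 tested (9 and 2 adjusted over the list alone, camera adjusted p = 6.2e-09). Of NRF2 targets 14 rose, 0 fell and 7 were not called of 21 tested (16 and 0 adjusted over the list alone, camera adjusted p = 4.9e-18). Among them were TRIM16L (log2 fold change 1.27, SE 0.10, edgeR adjusted p = 2.9e-22), GCLM (0.94, SE 0.07, 2.7e-19) and TXNRD1 (0.70, SE 0.06, 2.3e-18). FTH1 (log2 fold change 1.00, SE 0.15, edgeR adjusted p = 3.9e-04) rose. GPX4 (log2 fold change -0.54, SE 0.06, edgeR adjusted p = 1.7e-11) fell. With library size only GPX4 had a log2 fold change of -0.48 with a larger SE (0.20), and its call was lost (adjusted p = 0.169).

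Heat shock genes, by contrast, were little changed: 2 rose, 1 fell and 11 were not called of 14 tested (2 and 1 adjusted over the list alone, camera adjusted p = 0.0900). The list was called without sh-LUC DHA replicate 2 (camera adjusted p = 0.0163). Mitosis genes were not called as a list either: 4 rose, 1 fell and 17 were not called of 22 tested (4 and 1 adjusted over the list alone, camera adjusted p = 0.530). PTGS2 stood at 21.9 ± 1.39 CPM against 19.1 ± 1.33 CPM (log2 fold change 0.19, SE 0.13, edgeR adjusted p = 0.365).

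Erastin in sh-IGFBP6 cells was examined to ask how cells with little IGFBP6 respond to the same block. Oxidant defence, heat shock, immediate early, metallothionein and autophagy genes rose, and mitosis and DNA replication genes fell. HMOX1 went from 5.89 ± 1.06 to 495 ± 82.4 CPM and FOS went from 10.1 ± 1.96 to 354 ± 83.3 CPM. Amino acid stress genes rose less than in sh-LUC cells.

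In all, 2226 genes rose and 2178 fell, 442 and 185 of them by at least 2-fold, and 4354 were called without replicate 3. Of the calls 50.5% were rises, against 23.1% of 2728 calls when scaled by library size only, where the median of all genes moved to -0.19. The largest rises were HMOX1 (log2 fold change 6.26, SE 0.17, edgeR adjusted p = 1.0e-15), ARC (5.67, SE 0.15, 2.6e-61), NR4A1 (5.66, SE 0.19, 2.2e-53) and FOS (5.29, SE 0.11, 7.1e-59), besides MT-RNR1 and MT-RNR2, whose level in this group came from replicate 3. The largest falls were the histone genes H3C12 (log2 fold change -2.87, SE 0.12, edgeR adjusted p = 1.0e-31), H2AC4 (-2.71, SE 0.10, 7.9e-49), H2BC11 (-2.29, SE 0.09, 3.3e-48), H3C13 (-2.24, SE 0.13, 2.2e-32) and H2BC14 (-2.21, SE 0.10, 1.0e-42), and the helicase gene PIF1 (-2.25, SE 0.19, 7.0e-19).

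Of NRF2 targets 18 rose, 0 fell and 3 were not called of 21 tested (18 and 0 adjusted over the list alone, camera adjusted p = 7.5e-16). Among them were TXNRD1 (log2 fold change 1.35, SE 0.06, edgeR adjusted p = 5.0e-40), GCLM (2.16, SE 0.08, 3.7e-38) and UGDH (1.44, SE 0.08, 2.4e-34). SLC7A11 (log2 fold change 1.15, SE 0.06, edgeR adjusted p = 4.1e-31) and PTGS2 (1.98, SE 0.09, 9.5e-41) rose, as did FTH1 (2.58, SE 0.16, 2.4e-08) and AIFM2 (0.94, SE 0.10, 3.1e-13), which encodes a ferroptosis suppressor. Of the integrated stress response 17 rose, 0 fell and 7 were not called of 24 tested (18 and 0 adjusted over the list alone, camera adjusted p = 7.7e-11). Among them were PPP1R15A (log2 fold change 1.96, SE 0.06, edgeR adjusted p = 1.4e-50), ATF3 (3.14, SE 0.16, 1.2e-36) and CEBPB (1.25, SE 0.08, 4.0e-28). Of the aminoacyl-tRNA synthetases 6 rose, 3 fell and 11 were not called of 20 tested (6 and 4 adjusted over the list alone, camera adjusted p = 0.183). Of endoplasmic reticulum chaperones 11 rose, 0 fell and 11 were not called of 22 tested (14 and 0 adjusted over the list alone, camera adjusted p = 4.4e-06), a median of 0.27 that turned to -0.02 when scaled by library size only.

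Metallothioneins rose: 6 rose, 0 fell and 0 were not called of 6 tested (6 and 0 adjusted over the list alone, camera adjusted p = 6.5e-09). MT1X (log2 fold change 3.30, SE 0.14, edgeR adjusted p = 1.4e-38) and MT1E (2.37, SE 0.09, 1.6e-33) led them. Of heat shock genes 12 rose, 0 fell and 2 were not called of 14 tested (13 and 0 adjusted over the list alone, camera adjusted p = 3.8e-11). Among them were DNAJB1 (log2 fold change 1.75, SE 0.07, edgeR adjusted p = 1.0e-37) and HSPA1A (3.68, SE 0.14, 9.0e-31). Of immediate early genes 13 rose, 1 fell and 3 were not called of 17 tested (13 and 1 adjusted over the list alone, camera adjusted p = 6.1e-13). In it ZFP36 (log2 fold change 3.51, SE 0.12, edgeR adjusted p = 1.3e-52) and JUN (1.69, SE 0.06, 5.5e-48) rose and CCN1 (-0.54, SE 0.06, 1.9e-12) fell. Of autophagy and lysosome genes 16 rose, 0 fell and 5 were not called of 21 tested (16 and 0 adjusted over the list alone, camera adjusted p = 2.3e-08). Among them were SQSTM1 (log2 fold change 1.66, SE 0.06, edgeR adjusted p = 3.7e-49), GABARAPL1 (2.36, SE 0.12, 2.8e-35) and MAP1LC3B (1.09, SE 0.08, 5.6e-23). Of the NF-kB list 18 rose, 0 fell and 3 were not called of 21 tested (18 and 2 adjusted over the list alone, camera adjusted p = 1.9e-06). Of the mesenchymal list 20 rose, 4 fell and 7 were not called of 31 tested (20 and 4 adjusted over the list alone, camera adjusted p = 2.2e-05). In it SNAI1 (log2 fold change 2.88, SE 0.27, edgeR adjusted p = 2.6e-17) rose.

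Every mitosis gene tested fell: 0 rose, 22 fell and 0 were not called of 22 tested (0 and 22 adjusted over the list alone, camera adjusted p = 3.6e-17). KIF20A (log2 fold change -1.12, SE 0.08, edgeR adjusted p = 2.2e-25) and MKI67 (-0.85, SE 0.06, 3.9e-25) were examples. Of DNA replication genes 0 rose, 22 fell and 2 were not called of 24 tested (0 and 23 adjusted over the list alone, camera adjusted p = 1.9e-11). Among them were FEN1 (log2 fold change -0.64, SE 0.07, edgeR adjusted p = 1.3e-13) and MCM3 (-0.49, SE 0.06, 2.4e-12). Of the sterol list 1 rose, 17 fell and 7 were not called of 25 tested (1 and 19 adjusted over the list alone, camera adjusted p = 1.2e-07, adjusted p = 0.0998 with an estimated correlation). Scaled by library size only, falls were larger, at -0.91 for CCN1, -0.96 for FEN1 and -0.86 for MCM3.

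DHA in sh-IGFBP6 cells was examined to ask how the same cells respond to the fatty acid. More genes were called than in sh-LUC cells. NRF2 targets rose, as they did in sh-LUC cells. Chaperones, cytokines and autophagy genes also rose, and mitosis and histone genes fell. HMOX1 went from 5.89 ± 1.06 to 470.0 ± 10.1 CPM and PTGS2 went from 36.0 ± 2.00 to 240.4 ± 17.4 CPM.

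In all, 2644 genes rose and 2558 fell, 363 and 417 of them by at least 2-fold, and 5250 were called without replicate 3 of sh-IGFBP6 erastin. Of the calls 50.8% were rises, against 33.3% of 2579 calls when scaled by library size only. The largest rises were HMOX1 (log2 fold change 6.28, SE 0.16, edgeR adjusted p = 4.2e-16), ANGPTL4 (4.52, SE 0.17, 7.0e-41), HSPA1A (4.25, SE 0.13, 7.4e-36), HSPA1B (3.80, SE 0.12, 6.6e-14) and BEST1 (3.58, SE 0.27, 8.6e-23). The largest falls were CAVIN2 (log2 fold change -3.73, SE 0.08, edgeR adjusted p = 1.1e-71), a caveola gene, CPED1 (-2.24, SE 0.24, 6.8e-14), RIMS2 (-2.20, SE 0.17, 4.2e-23), LMO3 (-2.14, SE 0.14, 1.6e-27) and COL5A2 (-2.12, SE 0.28, 1.6e-10).

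Of NRF2 targets 20 rose, 0 fell and 1 were not called of 21 tested (20 and 0 adjusted over the list alone, camera adjusted p = 1.2e-25). Among them were TXNRD1 (log2 fold change 1.97, SE 0.06, edgeR adjusted p = 1.2e-56), GCLM (2.52, SE 0.08, 2.6e-44), UGDH (1.76, SE 0.07, 9.3e-45) and SLC7A11 (1.61, SE 0.06, 2.8e-44). Of the glutathione list 12 rose, 4 fell and 8 were not called of 24 tested (12 and 5 adjusted over the list alone, camera adjusted p = 0.00360). In it GSR (log2 fold change 1.12, SE 0.06, edgeR adjusted p = 6.4e-32) rose. FTH1 (log2 fold change 2.49, SE 0.15, edgeR adjusted p = 1.8e-08), AIFM2 (1.46, SE 0.09, 4.8e-28) and TFRC (0.47, SE 0.05, 1.2e-12) rose. Scaled by library size, TFRC had a log2 fold change of 0.38 with a larger SE (0.24), and its call was lost (adjusted p = 0.289). Of endoplasmic reticulum chaperones 20 rose, 0 fell and 2 were not called of 22 tested (20 and 0 adjusted over the list alone, camera adjusted p = 2.7e-16). Among them were HSPA5 (log2 fold change 1.60, SE 0.06, edgeR adjusted p = 1.3e-50), HERPUD1 (1.84, SE 0.09, 4.6e-39) and PDIA4 (0.86, SE 0.06, 6.7e-28). Of heat shock genes 13 rose, 0 fell and 1 were not called of 14 tested (13 and 0 adjusted over the list alone, camera adjusted p = 7.3e-15).

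Of NF-kB targets, cytokines and chemokines 17 rose, 0 fell and 4 were not called of 21 tested (17 and 0 adjusted over the list alone, camera adjusted p = 8.5e-15). Among them were CXCL8 (log2 fold change 2.39, SE 0.09, edgeR adjusted p = 3.0e-51), IL1B (1.76, SE 0.07, 3.8e-40) and CCL2 (1.58, SE 0.09, 2.0e-33). Of autophagy and lysosome genes 17 rose, 0 fell and 4 were not called of 21 tested (18 and 0 adjusted over the list alone, camera adjusted p = 3.0e-09). Among them were SQSTM1 (log2 fold change 2.58, SE 0.06, edgeR adjusted p = 1.4e-70) and CTSD (0.97, SE 0.08, 1.1e-19). DDIT3 (log2 fold change 1.88, SE 0.13, edgeR adjusted p = 3.3e-25) and CEBPB (1.59, SE 0.07, 1.2e-39) rose. Of the integrated stress response list 11 rose, 2 fell and 11 were not called of 24 tested (11 and 2 adjusted over the list alone, camera adjusted p = 7.9e-05, adjusted p = 0.109 with an estimated correlation). Of immediate early genes 13 rose, 3 fell and 1 were not called of 17 tested (13 and 3 adjusted over the list alone, camera adjusted p = 5.7e-08). Of hypoxia genes 13 rose, 0 fell and 8 were not called of 21 tested (14 and 0 adjusted over the list alone, camera adjusted p = 4.1e-07). PLIN2 (log2 fold change 2.61, SE 0.08, edgeR adjusted p = 4.9e-59) and CPT1A (0.89, SE 0.07, 8.2e-21) rose and SCD (-1.23, SE 0.08, 8.5e-14) and FASN (-0.70, SE 0.06, 3.1e-19) fell. Of mitosis genes 0 rose, 22 fell and 0 were not called of 22 tested (0 and 22 adjusted over the list alone, camera adjusted p = 2.7e-16). In it KIF20A (log2 fold change -1.21, SE 0.07, edgeR adjusted p = 6.4e-30) and BUB1 (-0.83, SE 0.06, 2.0e-24) fell.

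**Figure D4:**
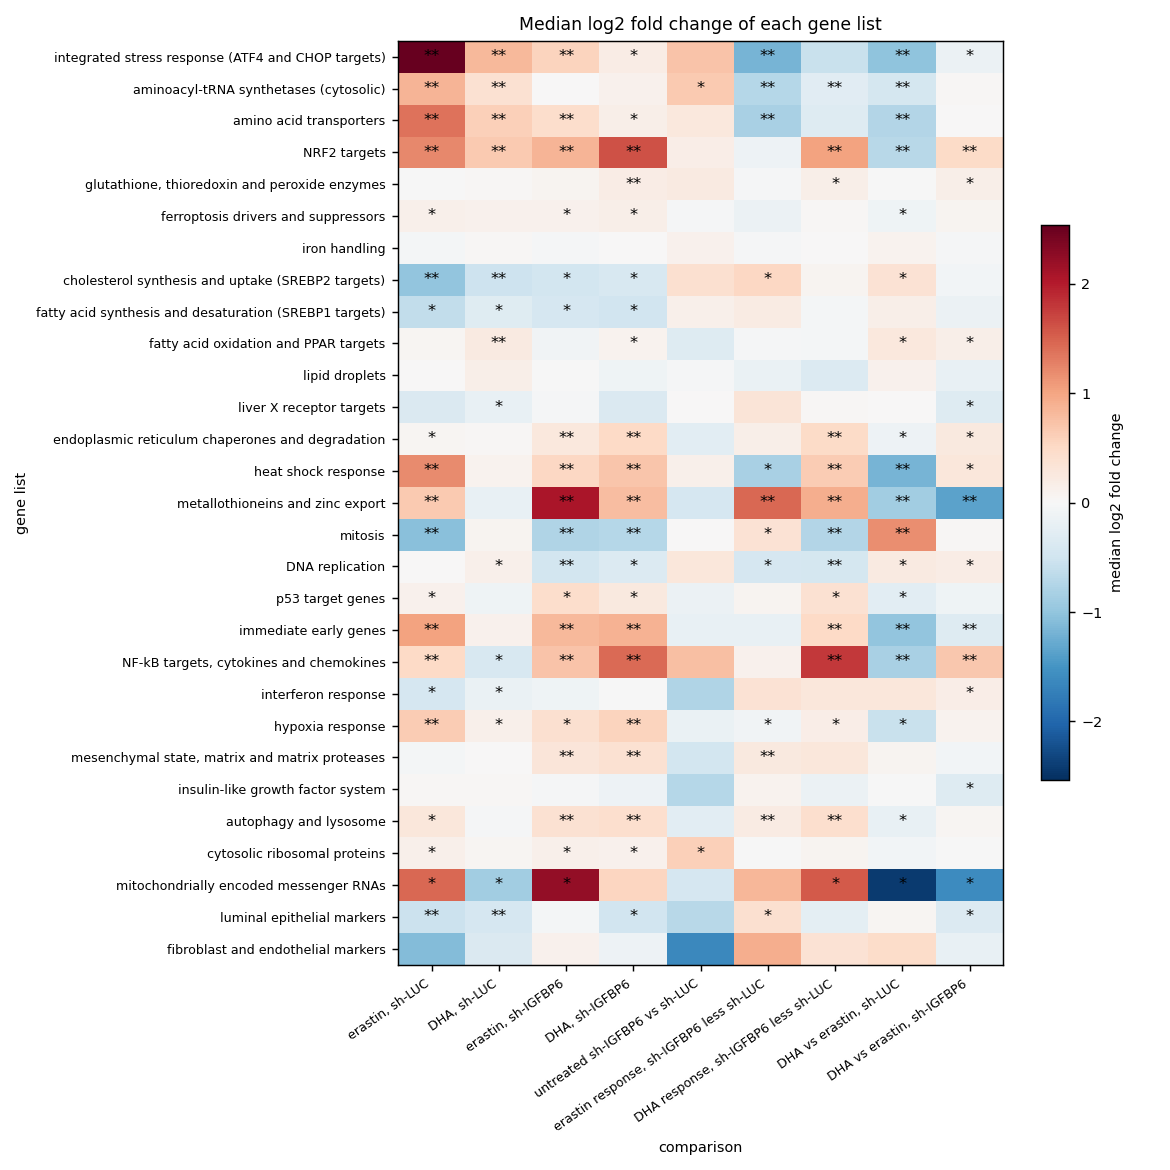
Median log2 fold change of 29 gene lists in the 9 comparisons, from blue (lower) to red (higher), with 1 star for a camera adjusted p below 0.05 and a second star where it held with an estimated correlation. The NF-kB list is strongest in the difference between lines in the DHA response (median 1.78), and the integrated stress response list in sh-LUC erastin (2.53).

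The erastin responses of the lines were subtracted, sh-IGFBP6 minus sh-LUC, to ask which responses depend on the line. The amino acid stress response to erastin was weaker in sh-IGFBP6 cells, and the metallothionein response was stronger. At 3973 genes the responses differed (2147 higher and 1826 lower), and at 3977 without replicate 3 of sh-IGFBP6 erastin. The count was 1327 when scaled by library size only, and the balance turned there (588 higher and 739 lower), without a filter (1388 and 1729), with only the libraries compared (2024 and 2101), without sh-IGFBP6 control replicate 3 (1731 and 1852) and without sh-IGFBP6 erastin replicate 1 (1421 and 1719).

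Of the integrated stress response 0 were higher, 19 lower and 5 were not called of 24 tested (0 and 20 adjusted over the list alone, camera adjusted p = 3.4e-13). Among them were MTHFD2 (log2 fold change difference -2.44, SE 0.13, edgeR adjusted p = 4.1e-31), PSAT1 (-2.02, SE 0.11, 1.1e-30), TRIB3 (-2.31, SE 0.16, 2.2e-24) and ATF3 (-2.41, SE 0.34, 4.1e-09). Of the aminoacyl-tRNA synthetases 1 were higher, 14 lower and 5 were not called of 20 tested (1 and 15 adjusted over the list alone, camera adjusted p = 4.1e-10). Among them were MARS1 (log2 fold change difference -1.49, SE 0.09, edgeR adjusted p = 1.5e-28) and IARS1 (-0.97, SE 0.08, 1.4e-19). Of the amino acid transporters 0 were higher, 9 lower and 5 were not called of 14 tested (0 and 11 adjusted over the list alone, camera adjusted p = 9.0e-08). Among them were SLC7A11 (log2 fold change difference -2.43, SE 0.10, edgeR adjusted p = 2.0e-40) and SLC7A1 (-1.42, SE 0.08, 1.3e-31). SLC7A11 began at 226 ± 27.1 CPM in sh-IGFBP6 and 58.7 ± 5.18 CPM in sh-LUC cells and reached 511 ± 29.5 and 708 ± 36.8 CPM. Lower responses were also measured for TFRC (log2 fold change difference -1.91, SE 0.09, edgeR adjusted p = 3.8e-40) and PTGS2 (-1.48, SE 0.14, 1.2e-15). Higher responses were measured for SAT1 (log2 fold change difference 2.24, SE 0.14, edgeR adjusted p = 4.1e-26), a polyamine enzyme gene, GABARAPL1 (2.01, SE 0.17, 8.4e-20) and MT1E (1.81, SE 0.13, 1.9e-18).

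Of metallothioneins 5 were higher, 0 lower and 1 were not called of 6 tested (5 and 0 adjusted over the list alone, camera adjusted p = 1.5e-04). Of heat shock genes 1 were higher, 11 lower and 2 were not called of 14 tested (1 and 11 adjusted over the list alone, camera adjusted p = 4.1e-10, adjusted p = 0.0587 with an estimated correlation). Among them were HSPD1 (log2 fold change difference -1.07, SE 0.08, edgeR adjusted p = 2.6e-22) and HSP90AA1 (-1.07, SE 0.10, 6.1e-18). Of the mesenchymal list 12 were higher, 2 lower and 17 were not called of 31 tested (14 and 2 adjusted over the list alone, camera adjusted p = 0.00491). Of DNA replication genes 0 were higher, 16 lower and 8 were not called of 24 tested (0 and 17 adjusted over the list alone, camera adjusted p = 1.2e-07, adjusted p = 0.0860 with an estimated correlation). The largest negative differences among genes with counts in every group were IL24 (log2 fold change difference -2.84, SE 0.42, edgeR adjusted p = 2.5e-08), FERMT3 (-2.64, SE 0.30, 1.7e-12) and ZFAND2A (-2.55, SE 0.24, 1.3e-16).

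The DHA responses were subtracted in the same way. The responses of cytokine, NRF2 target and chaperone genes were higher in sh-IGFBP6 cells, and those of mitosis genes lower. At 3124 genes the responses differed (1581 higher and 1543 lower), and at 3179 without replicate 3 of sh-IGFBP6 erastin. Of the calls 50.6% were higher, against 26.5% of 1041 calls when scaled by library size only, where the median of all genes moved to -0.14, and 32.3% of 2486 calls without a filter.

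Of the NF-kB list 16 were higher, 0 lower and 5 were not called of 21 tested (18 and 0 adjusted over the list alone, camera adjusted p = 7.4e-19). Among them were CXCL2 (log2 fold change difference 3.92, SE 0.64, edgeR adjusted p = 4.7e-07), CXCL8 (2.84, SE 0.24, 6.6e-19), NFKBIA (2.06, SE 0.15, 1.8e-22) and RELB (2.40, SE 0.20, 1.1e-19). Part of this difference was a fall in sh-LUC cells, where after DHA 1 rose, 6 fell and 14 were not called of 21 tested (1 and 6 adjusted over the list alone, camera adjusted p = 0.0198, adjusted p = 0.0620 with an estimated correlation). That fall was not called when only the libraries compared were fitted (camera adjusted p = 0.0813). Of NRF2 targets 14 were higher, 1 lower and 6 were not called of 21 tested (15 and 1 adjusted over the list alone, camera adjusted p = 4.4e-13). In it HMOX1 (log2 fold change difference 3.49, SE 0.46, edgeR adjusted p = 1.9e-05), TXNRD1 (1.28, SE 0.09, 8.2e-26) and GCLM (1.57, SE 0.11, 1.6e-21) had higher responses and SLC7A11 (-0.56, SE 0.09, 1.3e-06) a lower one. The level of SLC7A11 after DHA was higher in sh-IGFBP6 (693 ± 31.2 CPM) than in sh-LUC cells (266 ± 15.4 CPM). With library size only SLC7A11 had a log2 fold change difference of -0.69 with a larger SE (0.34), and its call was lost (adjusted p = 0.234). Of endoplasmic reticulum chaperones 19 were higher, 0 lower and 3 were not called of 22 tested (19 and 0 adjusted over the list alone, camera adjusted p = 1.1e-15). Among them were HSPA5 (log2 fold change difference 1.42, SE 0.08, edgeR adjusted p = 1.4e-31) and HERPUD1 (1.49, SE 0.13, 2.0e-18). Of heat shock genes 11 were higher, 0 lower and 3 were not called of 14 tested (11 and 0 adjusted over the list alone, camera adjusted p = 2.3e-14). Among them were DNAJB1 (log2 fold change difference 2.09, SE 0.09, edgeR adjusted p = 2.9e-34) and HSPA1A (3.73, SE 0.24, 4.6e-19).

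Every mitosis gene tested was lower: 0 were higher, 22 lower and 0 were not called of 22 tested (0 and 22 adjusted over the list alone, camera adjusted p = 1.2e-17). BUB1 (log2 fold change difference -0.91, SE 0.09, edgeR adjusted p = 1.2e-16) and AURKA (-0.94, SE 0.10, 1.2e-14) were examples. Of DNA replication genes 1 were higher, 21 lower and 2 were not called of 24 tested (1 and 22 adjusted over the list alone, camera adjusted p = 3.6e-11). Of autophagy and lysosome genes 14 were higher, 0 lower and 7 were not called of 21 tested (14 and 0 adjusted over the list alone, camera adjusted p = 1.3e-08). Among them were SQSTM1 (log2 fold change difference 1.59, SE 0.09, edgeR adjusted p = 2.9e-33) and CTSD (1.27, SE 0.10, 1.0e-21). PTGS2 (log2 fold change difference 2.55, SE 0.16, edgeR adjusted p = 6.3e-27), CDKN1A (1.85, SE 0.11, 7.1e-29) and FTH1 (1.48, SE 0.21, 2.1e-04) were higher. Responses were lower for CAVIN2 (log2 fold change difference -2.81, SE 0.11, edgeR adjusted p = 7.8e-46), PHGDH (-2.42, SE 0.23, 6.5e-16), TFRC (-1.72, SE 0.08, 5.8e-37) and PSAT1 (-1.72, SE 0.11, 1.4e-25). TFRC began at 546 ± 37.3 CPM in sh-IGFBP6 and 98.7 ± 7.09 CPM in sh-LUC cells. After DHA it stood at 754 ± 30.7 and 448.5 ± 36.7 CPM, still higher in sh-IGFBP6.

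DHA was set against erastin within sh-LUC cells to ask which changes belong to 1 compound. Of 7618 genes that differed, 3943 were higher and 3675 lower with DHA (51.8% higher, against 73.5% of 5478 calls when scaled by library size only, median 0.17), and 7748 differed without replicate 3 of sh-IGFBP6 erastin. Stress genes were lower with DHA and mitosis genes higher. The largest negative differences were HSPA6 (log2 fold change -8.29, SE 0.23, edgeR adjusted p = 1.2e-12), HMOX1 (-5.20, SE 0.11, 1.0e-17) and ATF3 (-4.90, SE 0.12, 1.2e-67). The largest positive ones were SLCO4A1 (log2 fold change 2.57, SE 0.10, edgeR adjusted p = 1.0e-49), TRIM6 (2.32, SE 0.22, 3.4e-17) and the histone genes H2AC4 (2.44, SE 0.08, 1.8e-55) and H2BC14 (2.25, SE 0.11, 4.4e-39).

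Of heat shock genes 0 were higher, 14 lower and 0 were not called of 14 tested (0 and 14 adjusted over the list alone, camera adjusted p = 3.1e-19). Of the integrated stress response 0 were higher, 23 lower and 1 were not called of 24 tested (0 and 23 adjusted over the list alone, camera adjusted p = 1.5e-15). Of mitosis genes 22 were higher, 0 lower and 0 were not called of 22 tested (22 and 0 adjusted over the list alone, camera adjusted p = 1.9e-21). PTGS2 (log2 fold change -3.27, SE 0.08, edgeR adjusted p = 3.3e-68), CXCL8 (-2.68, SE 0.12, 1.1e-40) and SLC7A11 (-1.41, SE 0.06, 4.3e-42) were lower with DHA. Higher were ANGPTL4 (log2 fold change 1.13, SE 0.07, edgeR adjusted p = 4.5e-26), PDK4 (1.34, SE 0.10, 5.4e-23) and PLK1 (1.90, SE 0.08, 2.3e-47).

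In sh-IGFBP6 cells 3928 genes differed between the compounds (1986 higher and 1942 lower with DHA), and 3874 without replicate 3. The split was 50.6% higher, against 63.1% of 1541 calls when scaled by library size only. The count was 2592 without replicate 1 of sh-IGFBP6 erastin. HMOX1 did not differ (470.0 ± 10.1 and 495 ± 82.4 CPM). The largest positive differences were ANGPTL4 (log2 fold change 2.48, SE 0.13, edgeR adjusted p = 4.6e-30), COL7A1 (1.98, SE 0.15, 9.8e-08), CXCL3 (1.87, SE 0.16, 1.3e-18) and CXCL2 (1.76, SE 0.16, 3.5e-18). The largest negative ones were ARC (log2 fold change -4.04, SE 0.12, edgeR adjusted p = 4.5e-57), CDKN1C (-2.92, SE 0.15, 1.0e-35), NR4A1 (-2.88, SE 0.13, 1.1e-41) and EGR1 (-2.84, SE 0.10, 4.4e-14).

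Of NRF2 targets 17 were higher, 0 lower and 4 were not called of 21 tested (17 and 0 adjusted over the list alone, camera adjusted p = 2.3e-06). Of the NF-kB list 16 were higher, 0 lower and 5 were not called of 21 tested (16 and 0 adjusted over the list alone, camera adjusted p = 2.3e-06). Of metallothioneins 0 were higher, 5 lower and 1 were not called of 6 tested (0 and 5 adjusted over the list alone, camera adjusted p = 1.1e-05). Of immediate early genes 1 were higher, 10 lower and 6 were not called of 17 tested (1 and 10 adjusted over the list alone, camera adjusted p = 2.2e-06). PLIN2 (log2 fold change 1.11, SE 0.07, edgeR adjusted p = 5.7e-28) and HSPA5 (1.07, SE 0.06, 1.6e-32) were higher with DHA and FOS (-2.57, SE 0.08, 1.5e-45) and MT1E (-2.10, SE 0.08, 5.2e-31) lower.

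Across all 15189 tested genes the erastin responses of the lines had a correlation of 0.356, and the DHA responses 0.172. Both depended on the genes kept: without a filter they were 0.092 and 0.019, and over 11518 genes with at least 5 CPM, a choice made after the data were seen, 0.475 and 0.27. Of 2693 genes called for erastin in both lines, 83.7% changed in the same direction. Of 1306 called for DHA in both, 75.7% did. Erastin and DHA had a correlation of 0.459 within sh-LUC and 0.609 within sh-IGFBP6 cells. These last pairs share their controls, which alone gave simulated correlations of 0.703 and 0.495, with covariances of 0.0643 against a measured 0.147 and 0.0507 against 0.204. Controls of 3 could not be divided into 2 parts of at least 2, so part of the excess may come from the shared controls. Genes called up in both compounds numbered 536 in sh-LUC, where n1 × n2 / N gave 232, and 1326 in sh-IGFBP6, where it gave 387.5.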

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

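Of the tests in this part, those of line labels, another cell line, the label of replicate 3, mitochondrial ribosomal RNA, scaling, depth as the whole cause and untreated level were chosen only after the result was seen, as were the splits of libraries except those for the erastin difference. The test of scaling replaced an earlier one on 3 lists, whose outcome a shift of all genes could not have changed, and that of untreated level replaced one on the median of untreated cells (0.76), where members went both ways and the list was not called.

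The results in this and the next paragraph came up because of a difference between groups: the same compound moved them differently in the 2 lines, by a test of the difference (sh-IGFBP6 minus sh-LUC). Lists are given where camera called them with both a preset and an estimated correlation, and p is that with the preset one. For erastin they were 3973 genes and 6 of the 12 lists called with the preset correlation. The median log2 differences were -1.18 for the integrated stress response (camera adjusted p = 3.4e-13), -0.73 for aminoacyl-tRNA synthetases (4.1e-10), -0.83 for amino acid transporters (9.0e-08), 1.45 for metallothioneins (1.5e-04), 0.25 for the mesenchymal list (0.00491) and 0.21 for autophagy (0.00660). Key genes with a smaller or more negative response were SLC7A11 (log2 fold change difference -2.43, SE 0.10, edgeR adjusted p = 2.0e-40), ATF3 (-2.41, SE 0.34, 4.1e-09), TRIB3 (-2.31, SE 0.16, 2.2e-24), HMOX1 (-1.73, SE 0.39, 0.00312), ACSL4 (-0.28, SE 0.10, 0.0224), PTGS2 (-1.48, SE 0.14, 1.2e-15), TFRC (-1.91, SE 0.09, 3.8e-40) and PLIN2 (-0.70, SE 0.13, 3.5e-06). Those with a larger or less negative one were AIFM2 (log2 fold change difference 0.56, SE 0.15, edgeR adjusted p = 0.00193), HMGCS1 (0.66, SE 0.11, 2.5e-07), SCD (1.15, SE 0.11, 2.5e-09), FADS2 (0.89, SE 0.09, 9.1e-14) and INSIG1 (0.42, SE 0.10, 9.1e-04). The direction was kept with larger SE and the call lost under library size only for ACSL4 (-0.47, SE 0.30, adjusted p = 0.395), PLIN2 (-0.84, SE 0.31, adjusted p = 0.0621), AIFM2 (0.50, SE 0.23, adjusted p = 0.171), HMGCS1 (0.48, SE 0.27, adjusted p = 0.288), SCD (0.89, SE 0.34, adjusted p = 0.0763), FADS2 (0.61, SE 0.33, adjusted p = 0.271) and INSIG1 (0.26, SE 0.25, adjusted p = 0.609). The ACSL4 call was also lost with DESeq2's Wald test (adjusted p = 0.0592) and without any 1 of 5 libraries (adjusted p from 0.0552 to 0.113).

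For DHA they were 3124 genes and, by the same rule, 10 of 14 lists. The median log2 differences were -0.28 for aminoacyl-tRNA synthetases (camera adjusted p = 2.1e-05), 1.03 for NRF2 targets (4.4e-13), 0.48 for endoplasmic reticulum chaperones (1.1e-15), 0.65 for heat shock (2.3e-14), 0.91 for metallothioneins (2.1e-05), -0.74 for mitosis (1.2e-17), -0.45 for DNA replication (3.6e-11), 0.51 for immediate early genes (5.9e-06), 1.78 for the NF-kB list (7.4e-19) and 0.42 for autophagy (1.3e-08). Key genes with a higher difference were DDIT3 (log2 fold change difference 1.39, SE 0.26, edgeR adjusted p = 1.7e-05), HMOX1 (3.49, SE 0.46, 1.9e-05), PTGS2 (2.55, SE 0.16, 6.3e-27), FTH1 (1.48, SE 0.21, 2.1e-04), AIFM2 (1.02, SE 0.14, 2.9e-09), PLIN2 (0.66, SE 0.12, 8.6e-06), ANGPTL4 (1.39, SE 0.27, 2.2e-05), HMGCS1 (0.59, SE 0.10, 1.7e-06) and INSIG1 (0.90, SE 0.11, 2.5e-11). Those with a lower one were SLC7A11 (log2 fold change difference -0.56, SE 0.09, edgeR adjusted p = 1.3e-06), TRIB3 (-0.60, SE 0.16, 0.00338) and TFRC (-1.72, SE 0.08, 5.8e-37). The direction was kept with larger SE and the call lost under library size only for SLC7A11 (-0.69, SE 0.34, adjusted p = 0.234), PLIN2 (0.54, SE 0.30, adjusted p = 0.323) and HMGCS1 (0.45, SE 0.26, adjusted p = 0.359).

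The line of counts that names no gene, which no comparison used, came up because its level lay above that of the control samples: it had 98.8 ± 21.7 CPM in sh-LUC erastin against 58.9 ± 3.66 in sh-LUC control (n = 3), while in sh-IGFBP6 erastin it had 2.701, 3.57 and 34.3 CPM against 73.8 ± 2.02 in sh-IGFBP6 control.

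The size of the difference between the untreated lines was weighed first. Library depth was counted against, since 91.9% of the calls were kept with each library thinned to 2708143 counts, and so was a wrong line label, since 0 libraries correlated better with the other line (own line at least 0.879, other line at most 0.772). Copy number may account for part: 25 of 282 windows of 50 neighbouring genes had medians outside all 100 shuffled orders, yet windows held only 7.09% of the variance, which counts against copy number as the whole cause. Another cell line is left open, because the 3 genes CDKN2A, CDKN2B and MTAP had 0 counts in both lines, which lines with the same loss would share. The hairpin is the biological candidate, and with 1 line per hairpin it cannot be told apart from other differences between the lines.

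Replicate 3 of sh-IGFBP6 erastin was weighed second. A wrong label was counted against, since its correlation with its own group (0.896) was 0.0148 above the next group, sh-IGFBP6 DHA (0.882), and at 122 of 152 genes that separate its mates from that group it lay nearer its mates. Incomplete removal of mitochondrial ribosomal RNA as the whole cause was counted against too, since mitochondrial messenger RNAs made up 16.3% of its other counts. Loss of cytoplasmic RNA is undecided: the median log2 ratio of nuclear-retained RNAs to its mates was 0.19, between the bounds set for the test. No biological explanation was tested.

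The DHA responses that differ between the lines were weighed last. A shift of all genes by the scaling as the whole cause was counted against, since calls went in both directions with TMM (1581 higher and 1543 lower) and with library size only (276 and 765), though the scaling moved their balance. A higher untreated level of the NF-kB list in sh-LUC as the whole source would leave DHA-treated lines near each other. After DHA 19 of 21 genes were higher in sh-IGFBP6 and 1 lower (median log2 difference 2.00). Untreated cells had a median of 0.76 in that direction, though members went both ways. These values argue against that source for the list. At equal depth 72.5% of the calls were kept, between the bounds written beforehand, so a part for library depth is undecided. With depth then equal, the 2448 genes called there count against unequal depth as the whole cause. The line is the biological candidate, and no test separated the hairpin from other differences between the lines.

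In splits of the libraries compared, the real assignment was the only 1 of 100 to call as many genes for the erastin difference (highest other 1797). It was also the only 1 of 100 for the DHA difference (highest other 546). The other splits exchanged libraries between the lines, which differed at 9811 genes untreated. That difference then added to the spread within groups and kept calls low, so these splits cannot decide on chance assignment. They were limited to assignments in which most libraries kept their label. In the other 7 comparisons the real assignment was the only 1 of 10, too few to decide. The highest other count there was 167, for DHA against erastin in sh-IGFBP6.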

How the results depend on the processing

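Results were recomputed under each alternative. For comparisons of 3 against 3 samples, leaving out a library left at least 2 per group. Of counts of genes 134 of 144 stayed within 1.5 times and 10 moved. Of counts of lists 141 stayed and 12 moved. A test was counted as reversed only if its direction changed and it was called under at least 1 of the 2 settings compared. A test called under neither counted as unchanged, whatever its direction. Of list tests 4161 were unchanged in this sense, 153 gained a call, 109 lost one and 2 reversed. Of tests of key genes, of the largest changes under the naming rule and of other genes named in the text these numbers were 6339, 26, 158 and 2, and of correlations 60 stayed and 4 moved.

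Counts of genes ran from 4571 to 7196 for erastin in sh-LUC (6967 in the test described), 756 to 2642 for DHA in sh-LUC (2546), 2728 to 4462 for erastin in sh-IGFBP6 (4404), 2579 to 5304 for DHA in sh-IGFBP6 (5202), 8113 to 10529 for the untreated lines (9811), 1327 to 4125 for the erastin difference (3973), 1041 to 3221 for the DHA difference (3124), 5478 to 8011 for DHA against erastin in sh-LUC (7618) and 1541 to 3940 in sh-IGFBP6 (3928). Library size only gave each lowest count, which moved for all but the untreated lines and sh-LUC DHA against erastin. DESeq2's Wald test gave 1565 for DHA in sh-LUC and 2422 for DHA against erastin in sh-IGFBP6. Leaving out each library gave 2592 to 3874 for the latter, lowest without replicate 1 of sh-IGFBP6 erastin. In each of the 9 comparisons the balance of higher and lower calls turned under at least 1 alternative. Without a filter, which tests other genes too, the share of higher calls went from 50.8% to 45.5% for DHA in sh-IGFBP6 and from 50.6% to 44.1% for DHA against erastin there. The cause was not tested.

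Lists called numbered 20, 14, 19, 21, 2, 12, 14, 18 and 15 in the same order. With an estimated correlation they were 12 and 7 in sh-LUC for erastin and DHA, 12 and 11 in sh-IGFBP6, 0 for the untreated lines, 6 for the erastin difference, and 9 and 4 for DHA against erastin in sh-LUC and sh-IGFBP6. No filter gave 22 for DHA in sh-LUC and 9 for the untreated lines, for which fry gave 23. Leaving out each library gave 9 to 15 for DHA against erastin in sh-IGFBP6. The cause was not tested.

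Reversed results were, for erastin in sh-IGFBP6 with library size only, ribosomal proteins (median -0.23, camera adjusted p = 0.994), TFRC (-0.23, adjusted p = 0.540) and INSIG1 (-0.003, adjusted p = 0.996), and, for the erastin difference with fry, iron handling (median -0.024, fry adjusted p = 0.0327). The correlation of erastin responses between lines was 0.092 without a filter and 0.282 with the 1 CPM filter, and 0.319 to 0.352 without each library. For DHA it was 0.019 without a filter. The cause was not tested.

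With the replicate block the counts were 7026, 2642, 4394, 5304, 9842, 4101, 3221, 7708 and 3940 in the order above. It gained a call for INSIG1 after erastin in sh-LUC (adjusted p = 0.0448) and ended those of CHAC1 between the untreated lines (0.0516) and of MT-RNR2 (0.0540) and MT-RNR1 (0.0622) for the erastin difference, and changed no other call of a named gene. Samples share only a number: 45 pairs with the same number had correlations of deviations from -0.04 to 0.106 (median 0.005, 0.0015 for different numbers), 1 over 0.1.

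Depth limits genes of low level. In replicate 3 of sh-IGFBP6 erastin 13922 genes had a count. Folds of genes with few counts, such as IGFBP6 in its hairpin line, are the least certain.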

Other observations

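The tests of histone genes, of the likeness of DHA in sh-IGFBP6 to erastin in sh-LUC, of untreated stress response levels and of ANK2 were chosen only after the result was seen.

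Replication-dependent histone genes, a set of 34, fell after erastin. The set was put together because some of them were among the largest falls, so no test of the set is given. In sh-LUC cells 33 were called lower and 0 higher (median log2 fold change -1.52), and in sh-IGFBP6 cells 32 and 0 (median -1.45). After DHA 30 were called lower in sh-IGFBP6 cells (median -0.60), while in sh-LUC cells 14 were called higher and 0 lower (median 0.19). The DHA responses of the lines differed at 30 of these genes, all lower in sh-IGFBP6 (median difference -0.76). The hypothesis that histone genes fall with DNA replication genes after erastin was tested. Both fell in 1 line, sh-IGFBP6 (DNA replication median -0.46, camera adjusted p = 1.9e-11), while in sh-LUC cells 10 DNA replication genes fell and 2 rose without a shift of the list (median 0.02, camera adjusted p = 0.523), which counts against it. A first version of this test counted only lines in which histone genes fell (2) and was replaced because it did not look at DNA replication genes. The set holds near-identical copies, so single members are uncertain.

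DHA in sh-IGFBP6 cells moved genes more as erastin did in sh-LUC cells than as DHA did there. Over 11518 genes with a mean of at least 5 CPM, the noise-corrected correlation was 0.487 with erastin in sh-LUC and 0.353 with DHA in sh-LUC, a difference of 0.134. Without each of 18 libraries in turn the difference ran from 0.109 to 0.16. Over all tested genes the uncorrected correlation with erastin in sh-LUC was 0.326, and 81.7% of 3094 genes called in both changed the same way. Erastin in sh-IGFBP6 and DHA in sh-LUC had a correlation of -0.034, with 47.1% of 1084 genes moving the same way.

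The smaller erastin response of stress response genes in sh-IGFBP6 might come from a higher untreated level, though that list was not called between the untreated lines (15 genes higher and 6 lower of 24, median log2 difference 0.72, camera adjusted p = 0.145). If so, erastin-treated lines would end near each other. Their median difference was -0.76, with 18 of 24 genes called lower and 2 higher in sh-IGFBP6, which counts against a higher starting level as the whole cause.

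The line of counts that names no gene opens with coordinates and follows a blank line of ANK2. Of 23 distinct coordinates 4 lay outside ANK2 of the annotation, against the bound as written. That bound was wrong, because the deposited table holds version 20 of the gene and the annotation version 17, so whether it is ANK2 is undecided and may stay so. In sh-IGFBP6 it had 73.8 ± 2.02 CPM untreated and 55.4 ± 13.2 with DHA, and with erastin 2.701, 3.57 and 34.3 CPM, from 20, 17 and 9 counts.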
